A study of Saccharomyces cerevisiae with 27 samples.

How the data were processed

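Log-phase Saccharomyces cerevisiae was studied in 4 anchor-away strains, in which a protein fused to the FRB domain is pulled out of the nucleus when rapamycin is added. The strains are WT, hst34 (HST4 deleted, HST3 fused to FRB), rrp6 (RRP6 fused to FRB) and hst34rrp6 (all 3 changes). Hst3 and Hst4 are histone deacetylases that act on lysine 56 of histone H3, and Rrp6 is the nuclear subunit of the RNA exosome. Cells grew in rich medium at 30 °C and received rapamycin 3 h before harvest, per the labels' protocols. Of 27 samples, 20 have values here: 8 RNA-seq, 8 DRIP-seq and 4 Break-seq libraries, with 2 per group. The 7 NET-seq samples, 4 of WT and 3 of hst34, are not analysed here.

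RNA-seq measured total RNA after removal of ribosomal RNA, with Schizosaccharomyces pombe cells added 1:6 at harvest as a spike-in. DRIP-seq measured DNA from RNA-DNA hybrids, enriched with the S9.6 antibody after digestion of 50 µg of DNA by restriction enzymes, with or without 30 U of RNase H, which removes the RNA strand of hybrids; libraries had 13 PCR cycles. Break-seq labels DNA ends in agarose plugs to capture breaks. Reads were 75 bp. The submitters' processing notes name Bowtie2, TopHat2 and SAMtools for RNA-seq with HTSeq 0.9.1, Bowtie2 and bedtools for DRIP-seq, Bowtie2 for Break-seq, and the build sacCer3. The role of each tool, the other versions, the filters and the use of strand are not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart. Genes with near-identical copies, which include most ribosomal protein genes, the TDH, ENO, SSA and HSP90 genes, are uncertain, because reads that fit both copies can be placed on either.

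Each of the 3 deposited tables holds a signal, not counts. The RNA signal is, per the table's title, normalised to the S. pombe spike-in and to gene length; it is the read count times 1 constant per library, per kb of a gene interval. The deposited DRIP signal is the read count per gene interval times 1 constant per library, not divided by length. The deposited Break-seq signal is the read count per peak times 1 constant per library, with the group means beside it; the basis of that scaling is not given in the sources used here. The peak list is 1 list for hst34 against WT, called with MACS per the table's title, so peaks were not called per sample. Where the design allowed for whole-number counts, the values turned out to be scaled, and the test for scaled values was used.

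Dividing each column by the value of 1 read returned whole reads for 100% of values in each of the 20 libraries, within 0.01 of a whole number. Recovered reads in genes ran from 5487526 to 10183415 per RNA library. In DRIP-seq they ran from 935412 to 2951246 in 7 libraries and reached 83303106 in the library WT 2. In Break-seq, reads in peaks ran from 63393 to 150851. PCR copies were not marked, so read numbers give counting error only. RNA values are given for 5297 genes and DRIP values for 5298, and 5297 have both. Of the 5298 genes, 5287 matched the RefSeq gene table, from which symbols were taken, and 11 did not. The deposited intervals have a median length of 1512 bp against 1263 bp for the open reading frames, and 4725 of 5287 open reading frames lie wholly inside their interval. Coordinates are those of the deposited tables, in sacCer3.

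Tests were limma 3.58.1 (R 4.3.3) with a trend on log2(value + pseudocount), with all 8 libraries of a table in 1 fit and Benjamini-Hochberg adjustment at 0.05. The pseudocount is the 5th percentile of positive values, 58.8 for RNA and 12.5 for DRIP. A fold change is therefore on the log2(value + pseudocount) scale, which understates the change of low genes. Genes above 0 in at least 2 libraries were tested, 5294 for RNA and 5298 for DRIP. The values were used as deposited, because in RNA centring would remove what the spike-in measures. For DRIP-seq the labels give no spike-in, so this reason holds for RNA only. The residual spread had a median of 0.18 log2 units in RNA and an infinite prior df. Genes of like mean level therefore carry the same standard error, which follows the trend. With each library centred the spread was 0.10 with a prior df of 7.53, and in DRIP it was 0.47 with a prior df of 4.34. Each ± beside a log2 fold change is the standard error from limma with n = 2 libraries per group. Whether the samples of a group came from separate cultures is not stated, so p-values measure the spread between these samples, which may be technical. In RNA that spread is pooled over genes, so a p-value does not measure the scatter of the gene's own libraries. Part of it is an offset per library that all genes share, so errors are not independent between genes.

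Lists of genes were tested with camera (limma) at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the 33 of 39 lists with at least 5 measured members. In RNA as deposited, the estimated correlation includes the offset per library that all genes share. A list that did not pass with it is therefore not shown to be unchanged. Counts of members are given over all genes tested and adjusted over the list alone. Genes named in the text are the sirtuin genes and RRP6; per comparison, up to 10 rising and 10 falling genes with the largest fold change among those with an adjusted p below 0.05, a mean above the lower quartile and groups that do not overlap; where fewer than 5 pass, the 10 with the smallest unadjusted p; per described list, up to 2 rising and 2 falling members that pass, or the 2 with the largest change where none pass; and the 10 peaks with the highest ratio, with any peak over a gene named by its change or p. Peaks over the sirtuin genes and RRP6 were added after their values were seen. The groups, tests, lists, naming rule and most alternatives were set before the data were examined. Comparisons that share WT libraries were set beside 100 simulations of unchanged groups. Peaks were compared with 10000 random placements of the same widths (1000 for the 50% of peaks with the higher ratio), and genes in peaks with 10000 random lists matched on mean level, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures used matplotlib 3.10.9.

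Alternatives were other pseudocounts and filters, centring, fits with only the groups compared, a replicate block, each library left out, and, chosen after seeing the data, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. In tests on simulated data shaped like the hst34 and WT libraries, changes were set only in genes with a mean signal above the median. Recovery among lower genes was not tested. Among the changed genes, limma recovered 40.3% of RNA genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold. On simulated DRIP data for the same comparison it recovered 0% of genes changed 1.5-fold or 2-fold, where edgeR also recovered 0%, and 16.7% of those changed 4-fold.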

Results

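The series asks how the sirtuins Hst3 and Hst4 act on transcripts, on RNA-DNA hybrids and on DNA breaks in yeast, and how these effects relate to RNA decay by Rrp6. RNA-seq covered WT, hst34, rrp6 and hst34rrp6, DRIP-seq covered WT and hst34 with and without RNase H, and Break-seq covered hst34 and WT. Each group had 2 libraries. Recovered reads in genes were 10183415 and 6514631 for WT RNA, 7643274 and 9976525 for hst34, 7759866 and 7413852 for rrp6, and 6674046 and 5487526 for hst34rrp6. DRIP libraries held 2951246 and 83303106 reads for WT, 1955771 and 1765999 for WT with RNase H, 1265755 and 1171635 for hst34, and 935412 and 1197354 for hst34 with RNase H. Break-seq libraries held 150851 and 140375 reads in peaks for hst34 and 86370 and 63393 for WT.

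HST4 (YDR191W, chromosome IV, 842301 to 843469), which the labels give as deleted in hst34 and hst34rrp6, had an RNA signal of 92.5 and 93.3 per kb in WT and 91.5 and 100.3 in rrp6. It was 9.69 and 0.726 in hst34, from 8 reads and 1 read, and 3.34 and 0 in hst34rrp6, from 3 reads and 0 reads. HST3 and RRP6 are depleted as proteins, so their RNA does not check the labels. HST3 RNA lay between 237 and 402 in all 8 libraries. RRP6 RNA was 666 and 741 in WT, 674 and 430 in hst34, 353 and 415 in rrp6, and 347 and 423 in hst34rrp6, and it fell by 0.79 ± 0.22 in rrp6 against WT (limma, adjusted p = 0.00538). Of the other sirtuin genes, HST2 fell by 0.78 ± 0.22 in rrp6 against WT (adjusted p = 0.00574). SIR2 RNA was 128 and 359 in WT, with no call in any comparison, and neither had HST1.

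**Figure D1:**
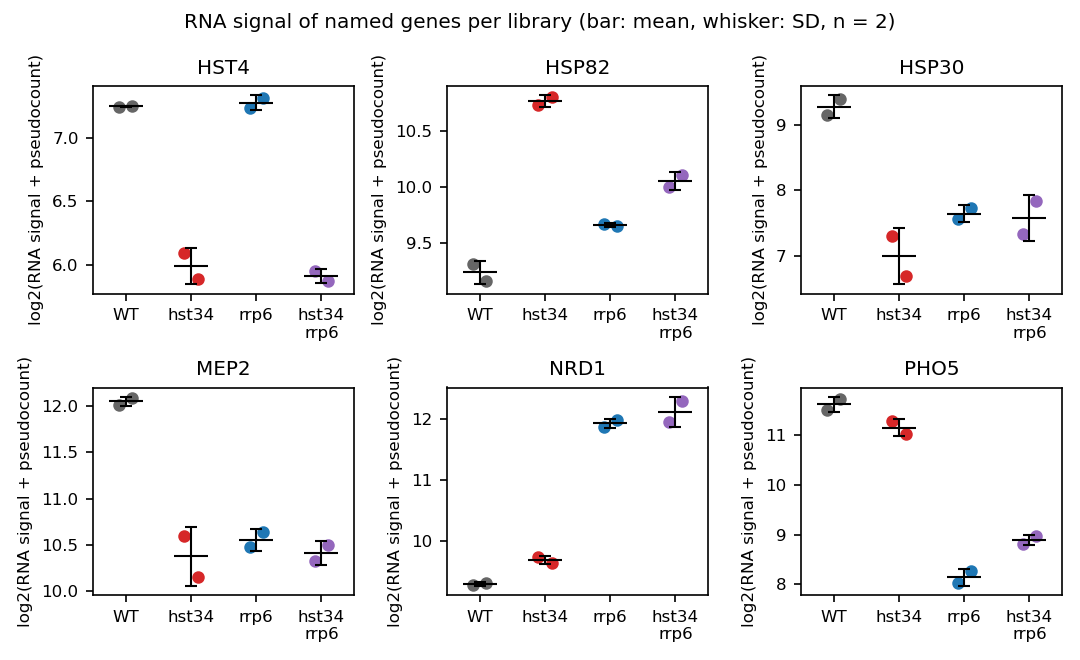
RNA signal of 6 named genes in each of the 8 RNA-seq libraries, as log2(signal + pseudocount) with a separate vertical scale per gene; points are libraries, bars are group means and whiskers are SD (n = 2). HST4 is lower in hst34 and hst34rrp6, MEP2 and HSP30 are lower than WT in all 3 mutant strains, and NRD1 is higher and PHO5 lower where Rrp6 is depleted.

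The scaling by spike-in set how far libraries of 1 strain lay apart. The median log2 signal differed between libraries 1 and 2 by 0.35 in hst34, −0.16 in WT, −0.14 in rrp6 and −0.18 in hst34rrp6. Against WT, the median level of all genes was −0.10 in hst34, 0.02 in rrp6 and 0.13 in hst34rrp6, and it was 0.11 in hst34rrp6 against rrp6. An exact two-sided permutation test gave p = 1 for hst34 and p = 0.667 for the other 3; 2 against 2 libraries cannot give less than 0.333. The sign for hst34 turned without hst34 2 (0.09), that for rrp6 without WT 1 (−0.06) or rrp6 2 (−0.06). The summed signal of all genes went the other way in the strains depleted of Rrp6: it was 7320510 and 8340130 in WT, 7982270 and 6218860 in hst34, 6410240 and 7050220 in rrp6, and 6215860 and 6825790 in hst34rrp6. On the log2 scale its difference from WT was −0.22 in rrp6 and −0.26 in hst34rrp6, each at the smallest exact permutation p of 0.333, and −0.15 in hst34 (exact permutation p = 0.667). For hst34rrp6 against rrp6 it was −0.05 (exact permutation p = 0.667). A global change was thus neither shown nor excluded with these libraries. Per gene, the median log2 fold change was −0.08, 0.00, 0.11, 0.10 and 0.17 for hst34 against WT, rrp6 against WT, hst34rrp6 against WT, hst34rrp6 against rrp6, and the interaction. With each library centred on its median these became 0.02, −0.02, −0.02, −0.01 and −0.03, so list medians are also given below relative to all genes of the same library.

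In hst34 against WT, some chaperone genes rose and some genes for nitrogen and phosphate uptake fell. HSP82 (YPL240C, chromosome XVI, 96397 to 98677), an Hsp90 chaperone, rose by a log2 fold change of 1.52 ± 0.22 (adjusted p = 4.51e-09), the Hsp70 gene SSA1 by 0.97 ± 0.22 and the mitochondrial disaggregase gene HSP78 by 0.90 ± 0.21. The stress-induced membrane protein gene HSP30 (YCR021C, chromosome III, 156030 to 157214) had the largest fall, −2.29 ± 0.20 (adjusted p = 6.75e-28). The ammonium permease gene MEP2 (−1.67 ± 0.22), the general amino acid permease gene GAP1 (−1.41 ± 0.22) and the polyamine transporter genes TPO2 (−1.64 ± 0.22) and TPO3 (−1.40 ± 0.22) fell as well. In all, limma called 106 of 5294 genes, 35 higher and 71 lower in hst34.

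Other genes with a large rise were HPF1 (1.03), which encodes a cell wall mannoprotein, the carbonic anhydrase gene NCE103 (0.94), the activator gene ADR1 (0.93), GPD1 of glycerol synthesis (0.88), BNA4 of the kynurenine pathway (0.84), DDR2 (0.78) and MBF1 (0.78). The other large falls were in TDA6 (−1.93), YLR297W (−1.58), STP4 (−1.49), RGS2 (−1.48) and YPS3 (−1.42), and HST4 itself fell by 1.25 ± 0.13.

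Of 25 heat shock and chaperone genes, 5 rose and 20 did not pass, with 11 rising adjusted over the list alone. Their median was 0.42, and camera gave an adjusted p of 1.45e-25; adjusted p = 0.644 with an estimated correlation. Of 23 genes under nitrogen catabolite repression, 9 fell and 14 did not pass, with 16 falling and 1 rising adjusted over the list alone. Their median was −0.54 (adjusted p = 1.21e-21; adjusted p = 0.729 with an estimated correlation). The same list lay below WT in both rrp6 libraries, by −0.57 and −0.51 relative to all genes, against −0.61 and −0.47 in the hst34 libraries. Of 16 phosphate regulon genes, 3 fell, 6 adjusted over the list alone; the glycerophosphoinositol permease gene GIT1 (−1.10 ± 0.21) and the phosphatase gene PHM8 (−1.10 ± 0.22) led the falls. This list had a median of −0.41 (adjusted p = 3.04e-10; adjusted p = 0.937 with an estimated correlation). Of 21 glycolysis and fermentation genes, 3 fell, 6 adjusted over the list alone, among them the enolase gene ENO1 (−1.03 ± 0.21) and the hexose transporter gene HXT1 (−0.82 ± 0.22), with a list median of −0.31 (adjusted p = 1.01e-05; adjusted p = 0.937 with an estimated correlation).

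None of 58 ribosome biogenesis genes passed in limma, singly or adjusted over the list alone, but 57 lay below 0, with a median of −0.38 (adjusted p = 1.61e-12; adjusted p = 0.937 with an estimated correlation), and with each library centred 16 fell. Of 36 general stress genes 2 rose, GPD1 and DDR2, or 5 adjusted over the list alone, with a median of 0.19 (adjusted p = 5.47e-09; adjusted p = 0.937 with an estimated correlation). Of 25 DNA damage response genes 1 rose, over all genes and adjusted over the list alone, PLM2 (0.75 ± 0.16), with a median of 0.12 (adjusted p = 1.01e-05; adjusted p = 0.937 with an estimated correlation). Of 30 G1/S genes 1 rose by both adjustments, the cyclin gene CLB6 (0.51 ± 0.14), with a median of 0.18 (adjusted p = 1.91e-06; adjusted p = 0.937 with an estimated correlation). Of 18 NAD biosynthesis genes 2 rose, BNA4 and BNA2 (0.82 ± 0.16), or 3 adjusted over the list alone, with a median of 0.01 (adjusted p = 0.0063; adjusted p = 0.937 with an estimated correlation). None of the 11 histone genes passed, while 1 fell adjusted over the list alone (median −0.20, adjusted p = 0.0417; adjusted p = 0.937 with an estimated correlation).

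The count depended on the libraries and the scaling. It was 53 without WT 1, 39 without WT 2, 460 without hst34 1 (25 higher, 435 lower), 61 without rrp6 1 and 63 without rrp6 2. Leaving out hst34 2 turned the balance to 89 higher and 40 lower, centring each library gave 184 higher and 214 lower, edgeR with TMM 575, DESeq2 with its own size factors 441, and a fit of the compared groups alone 30.

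In rrp6 against WT, REC104 and PHO5 were among the genes with the largest changes. The meiotic recombination gene REC104 (YHR157W, chromosome VIII, 412330 to 413418), normally silent in growing cells, rose by 3.43 ± 0.22 (adjusted p = 7.3e-52). The mitochondrial FAD transporter gene FLX1 rose by 3.26 ± 0.22, CTO1 by 3.25 ± 0.22, the glucose-response repressor gene RGT1 by 3.19 ± 0.22, and NRD1, which limits its own transcript through the Nrd1 termination complex, by 2.63 ± 0.22. The acid phosphatase gene PHO5 (YBR093C, chromosome II, 429459 to 430987) fell by 3.48 ± 0.22 (adjusted p = 1.02e-51), and the methylglyoxal reductase gene GRE2 (−2.77 ± 0.22) and the peroxisomal citrate synthase gene CIT2 (−2.04 ± 0.22) fell as well. limma called 591 genes, 240 higher and 351 lower. GRE1 (2.74), HEM4 (2.43), YPL245W (1.93), USE1 (1.92) and TAD2 (1.87) were the other genes with the largest rise. YNL134C (−2.58), PHM6 (−2.21), YLR297W (−2.15), HSP31 (−2.07), PRM7 (−1.91), RGS2 (−1.81) and YML131W (−1.76) were those with the largest fall.

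Of 16 phosphate regulon genes 13 fell and 0 rose in limma, or 14 and 1 adjusted over the list alone, with a median of −0.81 (adjusted p = 5.61e-20; adjusted p = 0.948 with an estimated correlation). Of 23 nitrogen catabolite genes 11 fell, 15 adjusted over the list alone, led by the allantoate permease gene DAL5 (−1.69 ± 0.21) and GAP1 (−1.55 ± 0.22), with a median of −0.54 (adjusted p = 9.19e-12; adjusted p = 0.948 with an estimated correlation). Of 21 glycolysis genes 9 fell, 13 adjusted over the list alone, with ENO1 at −1.58 ± 0.21 and TDH1 at −1.25 ± 0.22, while the pyruvate decarboxylase gene PDC5 rose by 0.82 ± 0.20 (list median −0.55, adjusted p = 2.9e-06; adjusted p = 0.948 with an estimated correlation). Of 34 oxidative phosphorylation genes 8 fell, 10 adjusted over the list alone, with the succinate dehydrogenase gene SDH3 at −1.61 ± 0.22 and QCR10 at −1.11 ± 0.22 (median −0.38, adjusted p = 4.38e-07; adjusted p = 0.948 with an estimated correlation). Of 17 genes of the TCA cycle 8 fell by both adjustments, with CIT2 and the aconitase gene ACO1 (−0.89 ± 0.22) leading (median −0.39, adjusted p = 6.59e-05; adjusted p = 0.948 with an estimated correlation). Of 18 NAD biosynthesis genes 5 fell, 6 adjusted over the list alone, led by BNA6 (−1.43 ± 0.22) and BNA3 (−0.94 ± 0.22), with a median of −0.42 (adjusted p = 9.1e-05; adjusted p = 0.948 with an estimated correlation).

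Of 16 genes attenuated through Nrd1, Nab3 and Sen1, 7 rose and 2 fell by both adjustments. NRD1 and the ribosomal protein gene RPL9B (1.57 ± 0.21) rose most, and the phosphate transporter gene PHO84 (−0.91 ± 0.20) and the glycogen phosphorylase gene GPH1 (−0.79 ± 0.18) fell. Their median was −0.02 although camera placed the list higher (adjusted p = 9.1e-05; adjusted p = 0.948 with an estimated correlation). Of 32 measured meiosis and sporulation genes 7 rose and 1 fell, or 8 and 5 adjusted over the list alone, with REC104 and the kinase gene SPS1 (1.38 ± 0.16) leading and SPO1 at −0.62 ± 0.14 (median 0.05, adjusted p = 0.0119; adjusted p = 0.948 with an estimated correlation). Of 11 histone genes 2 fell by both adjustments, HTA1 (−1.11 ± 0.21) and HHT2 (−0.79 ± 0.21), with a list median of −0.35 (adjusted p = 0.0289; adjusted p = 0.948 with an estimated correlation). Among chaperone genes HSP26 (1.70 ± 0.22) and BTN2 (0.59 ± 0.21) rose, and 23 of 25 did not pass, with 2 rising adjusted over the list alone (median 0.26, adjusted p = 0.0205; adjusted p = 0.948 with an estimated correlation). The attenuated genes lost their call in camera at the preset correlation too when libraries were centred (adjusted p = 0.0671), and so did the meiosis genes (adjusted p = 0.142).

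The count of 591 became 277 without WT 2 (146 higher, 131 lower), 269 without rrp6 1 (152 higher, 117 lower), 289 without rrp6 2, 1049 without hst34 1 and 1052 without hst34 2. It was 1763 with libraries centred, 1915 with edgeR and TMM, 1618 with DESeq2 and its own size factors, and 1071 with the compared groups alone.

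In hst34rrp6 against WT the genes with the largest changes were mostly those of rrp6 against WT. FLX1 rose by 3.41 ± 0.22, REC104 by 3.39 ± 0.22, RGT1 by 3.19 ± 0.22, CTO1 by 3.10 ± 0.22 and NRD1 by 2.82 ± 0.22, while GRE2 (−2.78 ± 0.22) and PHO5 (−2.73 ± 0.22) fell. ADR1, an activator of genes for non-fermentable carbon sources, rose by 2.31 ± 0.21 and the small chaperone gene HSP26 by 2.06 ± 0.22. GRE1 (2.91), HEM4 (2.41) and USE1 (2.27) also rose. PHM6 (−2.15), YNL134C (−2.12), GAP1 (−1.92), HSP30 (−1.70), PRM7 (−1.64), MEP2 (−1.64), SAM2 (−1.63) and PTR2 (−1.60) fell. HST4 fell by 1.33 ± 0.13. limma called 843 genes, 541 higher and 302 lower.

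Of 21 glycolysis genes 14 fell and 1 rose, or 19 and 1 adjusted over the list alone; HXT1 was at −1.54 ± 0.22, ENO1 at −1.46 ± 0.21 and PDC5 at 0.82 ± 0.20. The list had a median of −0.72 (adjusted p = 4.8e-15; adjusted p = 0.696 with an estimated correlation). Of 16 phosphate regulon genes 13 fell and 1 rose by both adjustments, the riser being the kinetochore gene CTF19 (0.61 ± 0.21), with a median of −0.80 (adjusted p = 3.16e-20; adjusted p = 0.696 with an estimated correlation). Of 135 cytosolic ribosomal protein genes 16 fell and 5 rose by both adjustments, with RPL18B (1.51 ± 0.22) and RPS14B (1.47 ± 0.21) highest and RPP1A (−0.79 ± 0.19) among the lowest. Their median was −0.20 (adjusted p = 2.48e-05; adjusted p = 0.985 with an estimated correlation), and with libraries centred 75 fell and 5 rose. Of 32 meiosis genes 12 rose, or 13 with 1 falling adjusted over the list alone (median 0.22, adjusted p = 0.000507; adjusted p = 0.985 with an estimated correlation), with SPS1 at 1.48 ± 0.16. Of 25 DNA damage genes 6 rose and 1 fell, 8 and 1 adjusted over the list alone, with DIN7 at 1.25 ± 0.17, PLM2 at 0.65 ± 0.16 and DDR48 at −0.78 ± 0.22 (median 0.33, adjusted p = 0.0469; adjusted p = 0.985 with an estimated correlation). Of 11 histone genes 3 fell, or 3 with 1 rising adjusted over the list alone, with HTA1 at −1.48 ± 0.21 (median −0.36, adjusted p = 0.00174; adjusted p = 0.985 with an estimated correlation). Of 24 M/G1 genes 9 fell, or 10 with 1 rising adjusted over the list alone, led by the daughter cell glucanase gene DSE4 (−1.04 ± 0.22) and the chitinase gene CTS1 (−0.94 ± 0.21), with a median of −0.32 (adjusted p = 2.48e-05; adjusted p = 0.985 with an estimated correlation).

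Leaving out a library gave 459 genes without WT 1, 418 without WT 2, 1429 without hst34 1, 1435 without hst34 2, 488 without hst34rrp6 1 and 373 without hst34rrp6 2. The excess of higher genes turned with the scaling, since centring gave 803 higher and 1248 lower, edgeR with TMM 1080 and 1155, and DESeq2 with its own size factors 804 and 1081; dropping the lowest 25% of genes gave 219 and 243.

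**Figure D2:**
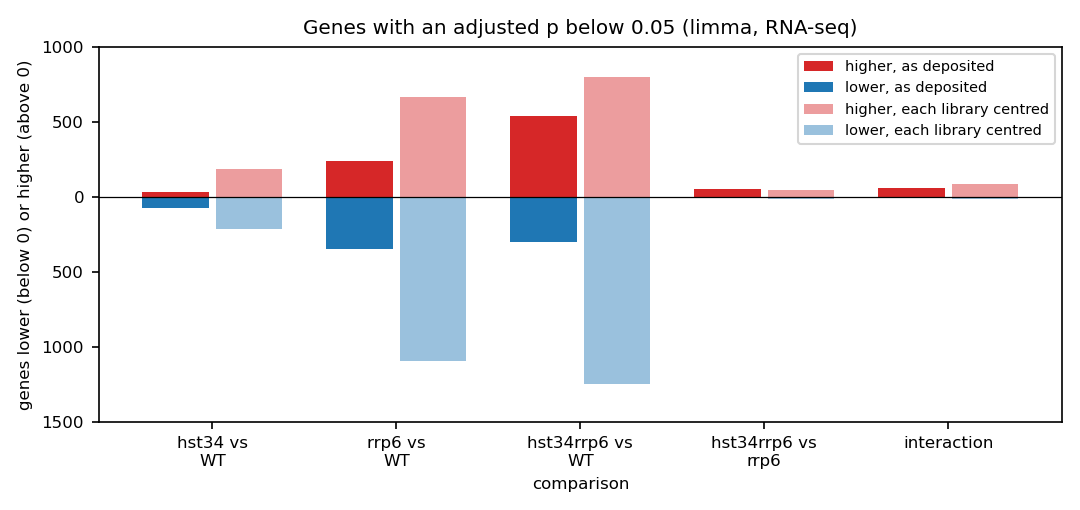
Number of genes with an adjusted p below 0.05 (limma) that were higher (above 0) or lower (below 0) in each of 5 RNA comparisons, with values as deposited (dark) and with each library centred on its median (pale). In hst34rrp6 against WT the balance was 541 higher and 302 lower as deposited, and 803 higher and 1248 lower with libraries centred.

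Nearly all genes called in hst34rrp6 against rrp6, with Rrp6 depleted in both strains, were higher in hst34rrp6. In this comparison CIT2 rose by 1.52 ± 0.22 (adjusted p = 7.03e-09), the small meiotic gene SPO24 by 1.48 ± 0.21, the arginine biosynthesis gene ARG1 by 1.40 ± 0.22, DPI8 by 1.33 ± 0.22 and ARO5 by 1.32 ± 0.21. The cell wall gene PIR3 (1.14), the vitamin B6 genes SNO1 (1.09) and SNZ1 (1.06), TPO2 (1.09) and the D-lactate dehydrogenase gene DLD3 (1.05) rose as well. HST4 fell by 1.36 ± 0.13. limma called 55 genes, 53 higher and 2 lower.

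Of 17 TCA cycle genes 2 rose, CIT2 and the mitochondrial citrate synthase gene CIT1 (0.86 ± 0.22), or 8 adjusted over the list alone, with a median of 0.26 and all 17 above 0 (adjusted p = 5.43e-09; adjusted p = 0.983 with an estimated correlation). Of 18 NAD biosynthesis genes 2 rose by both adjustments, BNA2 (0.99 ± 0.16) and BNA4 (0.79 ± 0.21), with a median of 0.15 (adjusted p = 0.0131; adjusted p = 0.983 with an estimated correlation). None of 25 DNA damage genes passed, 1 rose adjusted over the list alone and all 25 lay above 0, with a median of 0.25 (adjusted p = 8.03e-05; adjusted p = 0.983 with an estimated correlation). Of 135 ribosomal protein genes none passed by either adjustment, and 125 lay below 0 with a median of −0.16 (adjusted p = 6.17e-29; adjusted p = 0.983 with an estimated correlation); each of the hst34rrp6 libraries had this list lower relative to all genes, by −0.24 and −0.36 against WT, than the rrp6 libraries, by −0.03 and −0.05. None of 21 glycolysis genes passed and 2 fell adjusted over the list alone (median −0.20, adjusted p = 3.18e-12; adjusted p = 0.983 with an estimated correlation). None of 58 ribosome biogenesis genes passed by either adjustment (median −0.06, adjusted p = 1.86e-06; adjusted p = 0.983 with an estimated correlation).

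The count of 55 was 155 without hst34 1, 156 without hst34 2, 15 without rrp6 1, 19 without rrp6 2 and 11 without hst34rrp6 2, and 19 without the lowest 25% of genes. With libraries centred 49 were higher and 14 lower, with edgeR and TMM 132 and 49, with DESeq2 and its own size factors 106 and 121, and in a fit of the compared groups alone 150 and 20.

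The effect of losing Hst3 and Hst4 was then compared between cells with and without Rrp6, as an interaction. TDA6 had an interaction of 2.88 ± 0.28 (limma, adjusted p = 1.47e-20) and TPO2 one of 2.73 ± 0.31, HSP30 2.22 ± 0.28 and MEP2 1.53 ± 0.31. Their fall in hst34 against WT thus had no counterpart in hst34rrp6 against rrp6, where TPO2 rose by 1.09 ± 0.22. Against WT, HSP30 (−1.70 ± 0.20) and MEP2 (−1.64 ± 0.22) were lower in hst34rrp6 too. HSP82 had a negative interaction, −1.13 ± 0.31 (limma, adjusted p = 0.0295). limma called 63 genes, 61 above and 2 below 0. Over all genes the median interaction was 0.17, with 82.2% of genes above 0. Without hst34 2 it was 0.0007, with 50.2% above 0, so the upward shift of all genes was absent without that library. Of the 61, 43 were called lower in hst34 against WT and 16 were called higher in hst34rrp6 against rrp6. Of 23 nitrogen catabolite genes 6 passed, 12 adjusted over the list alone, all upwards, with a median of 0.67 against 0.17 for all genes (adjusted p = 4.39e-18; adjusted p = 0.926 with an estimated correlation). The count was 29 without WT 2, 270 without hst34 1, 16 without rrp6 1, 38 without rrp6 2 and 16 without hst34rrp6 2. With libraries centred 83 lay above and 16 below 0, with edgeR and TMM 133 and 31, and with DESeq2 and its own size factors 126 and 41.

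**Figure D3:**
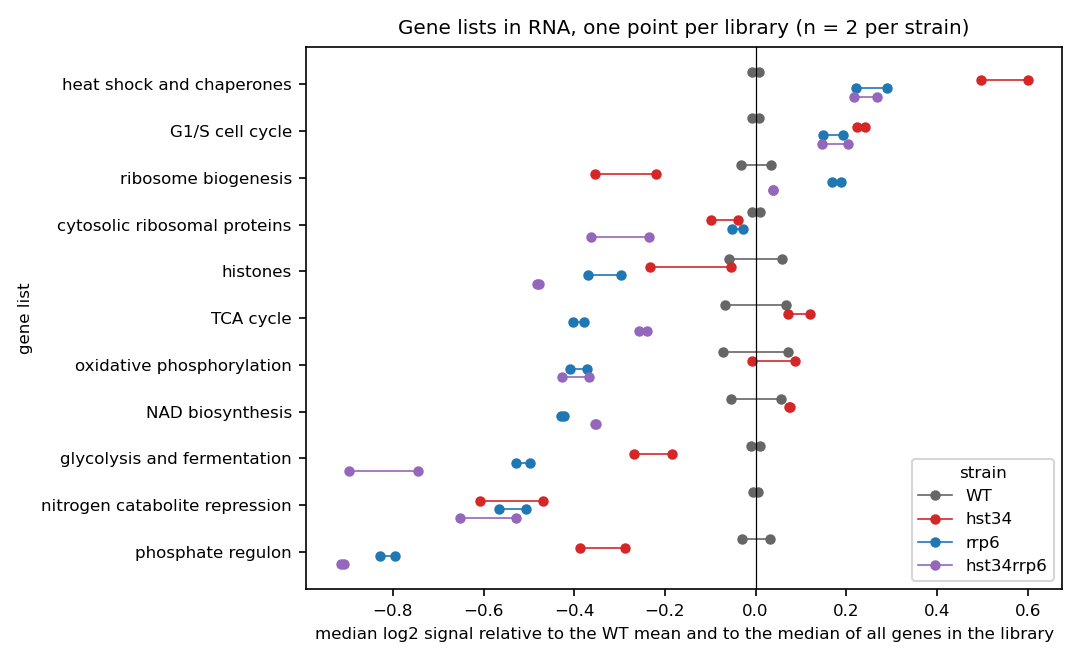
Median log2 RNA signal of 11 gene lists in each of the 8 libraries, relative to the WT mean and to the median of all genes in the library; each point is a library and a line joins the 2 libraries of a strain. The nitrogen catabolite list lies between −0.47 and −0.65 in all 6 mutant libraries, and the heat shock list is highest in hst34, at 0.50 and 0.60.

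Calls were compared between the mutant strains, which share the same WT libraries. Of the genes called in rrp6 and in hst34rrp6 against WT, 233 were higher and 213 lower in both. Independent lists of these sizes would share 24.5 and 20, and simulated unchanged groups with the shared WT libraries shared 3.16 and 0.52 on average. The fold changes correlated across genes with r = 0.90 (simulated 0.50) and a covariance of 0.15 (simulated 0.00703). For hst34 and rrp6, 6 genes were higher and 48 lower in both (independent lists 1.59 and 4.71, simulated 3.16 and 0.52), with r = 0.29, below the simulated 0.50, and a covariance of 0.0269 (simulated 0.00703). For hst34 and hst34rrp6, 23 were higher and 41 lower in both (independent lists 3.58 and 4.05, simulated 3.16 and 0.52), with r = 0.39, also below the simulated 0.50, and a covariance of 0.0374 (simulated 0.00703). Genes called in opposite directions numbered 2 for rrp6 and hst34rrp6, 1 for hst34 and rrp6, and 2 for hst34 and hst34rrp6 (independent lists 49.6, 5.54 and 9.25, simulated 0 for each). Part of each excess may come from the shared WT libraries, which are too few to split. Without shared libraries, hst34 against WT and hst34rrp6 against rrp6 had r = 0.25 across genes, 11 genes higher in both (independent lists 0.35) and 1 lower in both, HST4. A further 6 genes were called in opposite directions in these 2 comparisons (independent lists 0.724). Genes are not independent replicates.

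DRIP-seq asked where RNA-DNA hybrids differ between WT and hst34 cells. HST4 did not separate the strains in this table: its signal was 102 and 72.4 in WT, 53.4 and 58.7 in WT with RNase H, 15.3 and 53.1 in the libraries labelled hst34, and 79.9 and 99.5 in the libraries labelled hst34 with RNase H. Relative to the median gene, both untreated libraries labelled hst34 lay below WT (0.116 and 0.418 against 0.689 and 0.582), and both treated ones at or above WT (0.489 and 0.690 against 0.323 and 0.488). The WT libraries differed among themselves, with a SD over genes of 1.09 for the log2 ratio of WT 1 to WT 2 and 1.21 for the RNase H pair, against 0.42 and 0.51 for the libraries labelled hst34. WT 2, the library with 83303106 reads, correlated with WT 2 treated with RNase H at r = 0.991 and with WT 1 at r = 0.802.

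In the untreated libraries labelled hst34, genes with abundant transcripts had more DRIP signal relative to WT, though no single gene passed. Of 135 ribosomal protein genes 119 lay above 0, with a median of 0.75 against −0.02 for all genes (camera adjusted p = 7.69e-22; adjusted p = 0.779 with an estimated correlation); RPL8B was at 2.60 ± 1.03 and RPL5 at 2.56 ± 1.14. Of 21 glycolysis genes 18 lay above 0, with a median of 0.79 (adjusted p = 6.52e-05; adjusted p = 0.779 with an estimated correlation); TDH3 was at 3.20 ± 1.35 and PDC1 at 2.98 ± 1.46. Of 11 histone genes 10 lay above 0, with a median of 0.76 (adjusted p = 0.016; adjusted p = 0.825 with an estimated correlation). Relative to all genes this list stood at 0.62 in WT 1, near the libraries labelled hst34 (0.73 and 0.66), and at −0.62 in WT 2. Of 87 genes within 20 kb of a chromosome end 65 lay below 0, with a median of −0.31 (adjusted p = 0.0232; adjusted p = 0.779 with an estimated correlation). It stood, relative to all genes, at −0.31 in WT 1, between the libraries labelled hst34 (−0.425 and −0.249), and at 0.31 in WT 2. No member of these lists passed adjusted over the list alone.

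In DRIP-seq limma called 0 of 5298 genes between the libraries labelled hst34 and WT, with 140 at an unadjusted p under 0.05; edgeR called 0 with 147 and DESeq2 0 with 267 under the deposited scaling. The genes with the smallest unadjusted p included RPS12 (1.06 ± 0.29), MTR10 (−0.93 ± 0.27), HRT3 (−1.23 ± 0.35), MNT4 (−0.89 ± 0.26), SLS1 (−1.07 ± 0.33), DRS2 (−0.71 ± 0.22), PCL6 (−0.90 ± 0.28), RPS2 (2.01 ± 0.63) and UME1 (−1.16 ± 0.37), each with an adjusted p of 0.855. Without both WT number 2 libraries, an alternative chosen after seeing the data, 6 genes were called.

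RNase H treatment asks how much of the signal depends on RNA-DNA hybrids. The summed DRIP signal lay between 902159 and 1134350 in all 8 libraries and was not lower with RNase H. Totals this alike would hide a loss shared by all genes if libraries were scaled to a common total. The values below therefore show changes relative to other genes only, not how much of the signal came from hybrids. Untreated libraries 1 and 2 labelled hst34 correlated with their same-numbered RNase H libraries at r = 0.797 and 0.857. With WT 1 they correlated at 0.935 and 0.925, and with WT 2 at 0.740 and 0.795. In WT the same-numbered pairs had 0.949 and 0.991. Differences between the treated and untreated libraries labelled hst34 may thus have other sources than RNase H. In the libraries labelled hst34, ribosomal protein genes had less signal in those with RNase H, relative to other genes: 109 of 135 lay below 0, with a median of −0.42 while all genes had a median of 0.34 (adjusted p = 3.73e-22; adjusted p = 0.671 with an estimated correlation), and 2 fell adjusted over the list alone. RPS12 was at −1.59 ± 0.29 and RPL6B at −1.61 ± 0.30. Glycolysis genes had a median of −0.31 (adjusted p = 0.000932), ribosome biogenesis genes −0.09 (adjusted p = 7.42e-06), 14 galactose and alternative sugar genes 0.77 (adjusted p = 0.0164) and genes within 20 kb of a chromosome end 0.58 (adjusted p = 0.0122); for each of these 4 lists the adjusted p = 0.671 with an estimated correlation. In WT no list passed (lowest adjusted p = 0.528), and ribosomal protein genes had a median of 0.06 against 0.07 for all genes. The difference in the RNase H effect between the libraries labelled hst34 and those labelled WT, tested as an interaction, was −0.46 for ribosomal protein genes (adjusted p = 1.48e-20; adjusted p = 0.649 with an estimated correlation).

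Gene by gene and with libraries taken as unpaired, limma called 0 genes for RNase H in WT, in the libraries labelled hst34 and for the interaction, with 0, 541 and 92 genes at an unadjusted p under 0.05. edgeR called 0 for each, with 0, 490 and 95 under the deposited scaling. For RNase H in the libraries labelled hst34, DESeq2 called 90 genes (75 higher, 15 lower) under the deposited scaling and 53 (3 higher, 50 lower) with its own size factors, and limma on the compared groups alone called 1061. DESeq2 called 0 for the other 2. Without both WT number 2 libraries limma called 7 genes for RNase H in WT, 1040 in the libraries labelled hst34 and 48 for the interaction. The genes with the smallest unadjusted p in the libraries labelled hst34 were, besides RPS12 and RPL6B, AGP1 (1.45), UME1 (1.89), SLH1 (1.14), CSR2 (1.38), ROG3 (1.12), RHO5 (−2.14), TOF2 (−1.67) and RPL24A (−1.31), with an adjusted p of 0.452. In WT they included GCN20 (0.50), VHR1 (0.53), ATP22 (−0.62), GID7 (−0.55), RPN1 (0.48), AIM10 (0.51), SSP2 (−0.49), EXP1 (0.55) and ITR2 (0.43), with an adjusted p of 1. For the interaction they were NFU1 (−1.71), ROG3 (1.21), AGP1 (1.40), RPS12 (−1.44), UME1 (1.81), CSR2 (1.35), MED2 (−1.39), BET3 (−1.52), RPL6B (−1.41) and RPS0B (−1.08), also with an adjusted p of 1.

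RNA and DRIP-seq were compared across genes, which are not independent replicates. The WT RNA level correlated with the DRIP fold change of the libraries labelled hst34 against WT at a Spearman rho of 0.24, with the RNase H fold change in those libraries at −0.22 and with that in WT at −0.05. The first and second of these share the untreated libraries labelled hst34, for which simulated data without effects gave a covariance of −0.20 between the fold changes against −0.12 observed. The simulation gave each library the spread pooled over all groups. The shared libraries had less: the SD over genes of their log2 ratio was 0.42, against 1.09 for WT and 1.21 for WT with RNase H. The simulated value therefore overstates the part due to sharing and cannot tell how much of the observed covariance it explains. With the DRIP signal itself the rho was −0.11 in WT and 0.01 in the libraries labelled hst34. The RNA fold change of hst34 against WT correlated with the DRIP fold change at −0.13, and that of hst34rrp6 against rrp6 at −0.15. Per kb of interval, the rho of WT RNA level with DRIP signal was 0.158 and 0.155 in the untreated libraries labelled hst34, −0.009 and 0.049 in those with RNase H, 0.041 and −0.046 in WT and 0.036 and −0.053 in WT with RNase H. The median ribosomal protein gene had 2.36 and 2.54 times the signal per kb of the median gene in the untreated libraries labelled hst34, and at most 1.63 times in the other 6.

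**Figure D4:**
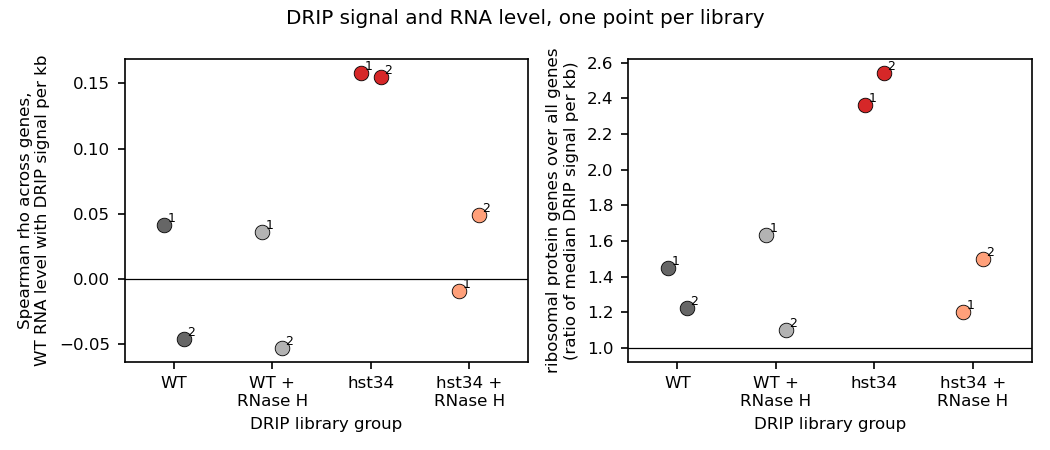
Spearman rho across genes between WT RNA level and DRIP signal per kb (left) and the ratio of median DRIP signal per kb of ribosomal protein genes to that of all genes (right), 1 point per DRIP-seq library with its number. Both untreated libraries labelled hst34 lie above the other 6, at 0.158 and 0.155 (left) and 2.36 and 2.54 (right).

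Break-seq peaks mark regions with more DNA ends in hst34 than in WT. The deposited list holds 239 peaks with a median width of 2250 bp (500 to 31750 bp), which cover 858500 bp or 7.12% of the genome length used. Over all peaks the deposited signal per kb was 164 ± 12.7 (SD, n = 2) in hst34 and 90.4 ± 2.26 in WT, with single libraries at 155 and 173 against 92.0 and 88.8. Both hst34 libraries exceeded both WT libraries in all 239 peaks, but the peaks were chosen for this difference on the same libraries, so it is not independent evidence. The ratio of the deposited means had a median of 1.71 (1.22 to 3.74), and 22 peaks had a ratio of at least 2. The fewest reads in any peak of any library were 28.

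The highest ratio, 3.74, was on chromosome VII, 460251 to 483500, over 9 genes that include PMA1, the plasma membrane proton pump gene, and LEU1. The next was chromosome VII, 1019001 to 1050750 (2.79), over 15 genes that include SLH1 and the ribonuclease gene RNH70. The others of the top 10 were on chromosome VII at 517501 to 519000 and 516251 to 517500 (MSB2 and SNU71) and at 1054001 to 1059250 (YOR1, BGL2 and UPA1), on chromosome IV at 836001 to 842250 (CCT6, SLY1 and RVB1), on chromosome XV at 696501 to 701750 (ULS1 and THI72), on chromosome XIII at 712501 to 722750 (ERG8 to TAF7, with the break repair gene MRE11) and 723251 to 742500 (with the RNase H gene RNH1), and on chromosome XVI at 900251 to 901250 (SMX3 and DPM1). A peak with a ratio of 1.996 lay over HST3 (chromosome XV, 378001 to 379000) and one of 1.39 over RRP6 (chromosome XV, 327501 to 331750). Of the other genes named above from RNA-seq and DRIP-seq, HSP78 lay in peaks with ratios of 1.78 and 1.84, DRS2 in one of 1.62, ATP22 in one of 1.72, RPL24A in one of 1.22 and SLH1 in the one of 2.79. Peaks flanked HST4 on both sides, at 836001 to 842250 and 843501 to 855750 on chromosome IV, with none over the gene.

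**Figure D5:**
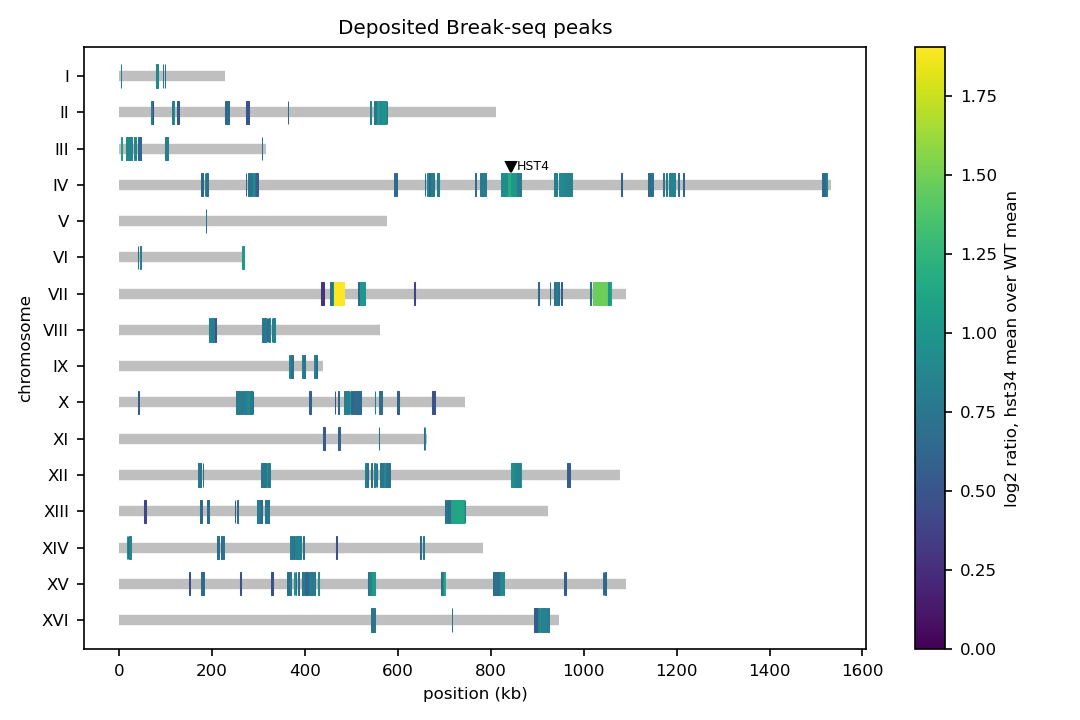
Map of the 239 deposited Break-seq peaks on the 16 chromosomes (position in kb), coloured by the log2 ratio of the deposited hst34 mean to the WT mean; the triangle marks HST4. Chromosome VII holds the peak with the highest ratio, 3.74, and chromosome V holds 1 peak.

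At least 1 bp of a gene interval lay in 234 of 239 peaks (97.9%), against a median of 221 (95% of placements 213 to 229) over 10000 random placements (permutation p = 0.0006, two-sided). Random placements could fall anywhere on a chromosome, repeats included, while the gene intervals held 0 retrotransposon ORFs and 0 tRNA genes. Regions where reads cannot be placed were not left out, so this difference does not show a preference for genes. With the stricter demand that over 50% of the peak lie in the gene, 134 peaks did, against 131 at random (permutation p = 0.7). Genes in peaks had a median log2 WT RNA level of 8.35, inside the random range of 8.18 to 8.52 (permutation p = 0.8), and neither their DRIP signal per kb nor their length stood apart (permutation p = 0.2 for each). Within 20 kb of a chromosome end lay 5.86% of peaks against 5.02% at random (permutation p = 0.6). By chromosome, peaks were fewest relative to length on V (1, 11.4 expected) and XI (5, 13.2 expected) and most frequent on X (27, 14.8 expected).

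The 542 genes that overlap peaks had a median RNA log2 fold change of −0.10 in hst34 against WT, at percentile 1.05 of random lists matched on mean level, and 0.08 in hst34rrp6 against rrp6, at percentile 0.27. Both positions depended on the overlap: for the 123 genes that hold at least 50% of a peak the percentiles were 44.1 and 94.4. In DRIP-seq their median was −0.03 for the libraries labelled hst34 against WT (percentile 74.9) and 0.42 for RNase H in the same strain by label (percentile 99.7; 97.0 for the 123 genes). Genes called in RNA-seq were not enriched in peaks: 10 of those called in hst34 against WT overlapped a peak against 10.9 for the share of all genes. The numbers were 44 against 60.5 in rrp6 and 72 against 86.3 in hst34rrp6 against WT. They were 5 against 5.63 in hst34rrp6 against rrp6 and 3 against 6.45 in the interaction.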

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

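The tests weighed for nitrogen catabolite genes were chosen only after the result was seen. The effect of losing Hst3 and Hst4 on RNA differed between cells with and without Rrp6 for 63 genes, by the limma interaction. Single genes with the largest difference were TDA6 (2.88), TPO2 (2.73), YLR297W (2.31), HSP30 (2.22), STP4 (2.15), TPO3 (1.97), CIT2 (1.97), COM2 (1.959), YPS3 (1.93) and CIP1 (1.79), with HSP82 (−1.13) the other way. For the gene lists that camera called at the preset correlation, none of which passed with an estimated correlation (lowest adjusted p = 0.926 with an estimated correlation), the median differences were −0.015 for ribosomal protein genes, 0.318 for ribosome biogenesis, −0.309 for heat shock, 0.056 for general stress, 0.239 for the TCA cycle and 0.665 for nitrogen catabolite genes. They were 0.548 for the phosphate regulon, −0.062 for G1/S genes, 0.381 for auxotrophic marker loci and 0.246 for genes within 20 kb of a chromosome end, while all genes had 0.17. With libraries centred as well, chosen after seeing the data, 1 list passed in camera with an estimated correlation (adjusted p = 0.0488). For the RNase H effect in DRIP-seq, libraries labelled hst34 against WT, the lists called at the preset correlation had median differences of −0.464 for ribosomal protein genes, −0.185 for ribosome biogenesis, −0.234 for glycolysis and 0.484 for genes within 20 kb of a chromosome end. With an estimated correlation none of these passed (adjusted p = 0.649, 0.886, 0.891 and 0.649).

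Of 23 nitrogen catabolite genes, limma called 9 lower in hst34 against WT, 0 lower in hst34rrp6 against rrp6 and 6 above 0 in the interaction, but camera did not call the list in hst34 (adjusted p = 0.729) or in the interaction (adjusted p = 0.926) with an estimated correlation. That estimate includes the offset that all genes of a library share, so it does not show that the list is unchanged. Scaling of the libraries does not account for the pattern in limma, since the list kept an interaction of 0.458 with each library centred, when all genes had −0.03. A difference that sets both WT libraries apart from every mutant strain, such as medium or harvest, needs the list to be low in rrp6 as well, and the higher of the rrp6 libraries had −0.506 relative to WT. A response to loss of Hst3 and Hst4 that loss of Rrp6 also sets off needs the same, so that this value does not favour either. Both explanations may hold and stay open.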

How the results depend on the processing

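Genes named by their change or p kept their direction in every alternative that gave them a test result. The sirtuin genes, RRP6 and genes named only as list members were not followed through the alternatives. For RNA, 1466 values stayed on their side of the threshold and 62 no longer passed; for DRIP, 801 stayed and 68 came to pass; of the other results, 201 stayed, 84 moved and 6 no longer passed. Leaving out 1 library at a time gave 39 to 460 genes for hst34 against WT, 269 to 1052 for rrp6, 373 to 1435 for hst34rrp6, 11 to 156 for hst34rrp6 against rrp6 and 16 to 270 for the interaction, and 0 to 0 in each DRIP comparison. The lone library left in a group was assumed to vary like the other groups. The median level of all genes then ran from −0.2922 to 0.0909 for hst34, −0.0608 to 0.1031 for rrp6, 0.0324 to 0.2227 for hst34rrp6 and 0.0112 to 0.2016 for hst34rrp6 against rrp6. The cause of these and the following shifts was not tested. In simulated DRIP data, with changes only in genes above the median signal, limma recovered 0% of 2-fold and 16.7% of 4-fold changes. There edgeR with TMM recovered 0% of both, so that changes of single genes may be missed. The fewest reads of any Break-seq peak were 28. A stricter threshold on the authors' peak significance was not run, because the deposited list has no such column.

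Libraries share only a number. With the replicate block, hst34 against WT gave 61 genes and hst34rrp6 against rrp6 gave 35, while the other counts stayed within 1.5 times. Deviations of same-numbered libraries correlated between groups at r from −0.198 to 0.114 in RNA. In DRIP the r was 0.94 between WT and WT with RNase H, and 0.123 to 0.27 between other groups. The unpaired test of RNase H in WT thus kept in its error a spread that same-numbered libraries shared. With a number effect fitted within each strain, chosen after seeing the data, DRIP counts were 1386 for the libraries labelled hst34 against WT and 0 for RNase H in WT. They were 1760 for RNase H in the libraries labelled hst34 and 234 for the interaction. By its construction this fit takes the spread between numbers out of the error between strains too, so the 1386 is not a test between separate libraries.

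In the order hst34, rrp6, hst34rrp6, hst34rrp6 against rrp6 and interaction, RNA counts were 106, 591, 843, 55 and 63. Centring each library gave 398, 1763, 2051, 63 and 99. Chosen after seeing the data, edgeR with TMM gave 575, 1915, 2235, 181 and 164 and DESeq2 with its own size factors 441, 1618, 1885, 227 and 167; DESeq2 with the deposited scaling gave 31 for hst34rrp6 against rrp6. Only the groups compared gave 30 for hst34, 1071 for rrp6 and 170 for hst34rrp6 against rrp6. Dropping the lowest 25% of genes, so that fewer were tested, gave 462 for hst34rrp6 and 19 for hst34rrp6 against rrp6. The level of hst34rrp6 against WT over the upper 50% of genes was −0.0206, and the median interaction of all genes was −0.0336 with libraries centred.

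In DRIP-seq, where limma called 0 genes, leaving out both WT number 2 libraries (chosen after seeing the data) gave 6 for the libraries labelled hst34 against WT, 7 for RNase H in WT, 1040 for RNase H in those labelled hst34 and 48 for the interaction. For RNase H in the libraries labelled hst34, only the groups compared gave 1061, and DESeq2, also added later, gave 90 with the deposited scaling and 53 with its own size factors. Among genes above the median WT RNA level, correlations of WT RNA level were −0.052 with DRIP signal in WT, 0.116 with that in the libraries labelled hst34, −0.013 with the RNase H fold change in WT and −0.285 with that in the libraries labelled hst34. The RNA fold changes of hst34 and of hst34rrp6 against rrp6 then correlated with the DRIP fold change at −0.048 and −0.113. Divided by interval length, DRIP signal gave −0.015 in WT and 0.158 in the libraries labelled hst34.

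Camera with an estimated correlation called 0 lists in every comparison, where the preset correlation called 14, 14, 14, 13 and 10 for RNA and 6, 0, 5 and 4 for DRIP. With libraries centred as well (chosen after seeing the data) it called 0, except for 1 in the RNA interaction. The lowest adjusted p in camera was then 0.0581 for hst34, 0.0903 for rrp6 and 0.107 for hst34rrp6. It was 0.337 for hst34rrp6 against rrp6 and 0.0488 for the interaction. Without centring these were 0.644, 0.948, 0.696, 0.983 and 0.926. In DRIP the lowest with centring was 0.343. With at least 50% of the peak inside the gene, 56.07% of peaks overlapped a gene, and the percentiles of peak genes were 44.05 for RNA in hst34, 94.4 for hst34rrp6 against rrp6 and 96.98 for RNase H in the DRIP libraries labelled hst34. Random lists not matched on level gave 2.59 and 2.82 for the first and second of these. In the 50% of peaks with the higher ratio, also added later, 117 peaks overlapped a gene against 111 over 1000 random placements (permutation p = 0.04). These placements too could fall in repeats.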

Other observations

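The tests weighed for the DRIP link to RNA level and for Break-seq signal were chosen only after the result was seen. Single members of some smaller gene groups changed in rrp6 against WT. Of 23 iron regulon genes 5 rose in rrp6 against WT, over all genes and adjusted over the list alone, led by the mRNA decay factor gene TIS11 (0.98 ± 0.17) and its paralog CTH1 (0.92 ± 0.22), but the list as a whole did not pass (median −0.16, adjusted p = 0.792). Of 14 galactose and alternative sugar genes 3 rose, or 3 with 1 falling adjusted over the list alone, led by the maltose activator gene MAL33 (1.097 ± 0.22) and the maltose transporter gene MAL11 (0.65 ± 0.15), and again the list did not pass (adjusted p = 0.103). Of 18 nuclear exosome and TRAMP genes AIR2 rose (0.89 ± 0.21) and RRP6 fell (−0.79 ± 0.22), and the list did not pass (median 0.20, adjusted p = 0.125). Of 23 sterol biosynthesis genes 3 fell, 5 adjusted over the list alone, led by ERG25 (−0.73 ± 0.21) and HMG2 (−0.70 ± 0.22), with a median of −0.18 (adjusted p = 0.0391; adjusted p = 0.948 with an estimated correlation).

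Marker loci and cell type genes served as checks on the strains. LEU2 fell in hst34 against WT (−0.97 ± 0.21) and had an interaction of 1.40 ± 0.30, and MET17 fell by 1.40 ± 0.22 in rrp6 and by 1.48 ± 0.22 in hst34rrp6 against WT. Of 6 a-cell genes, the pheromone gene MFA2 (−0.80 ± 0.19) and the protease gene BAR1 (−0.48 ± 0.10) fell in rrp6 against WT, and MFA1 rose in hst34rrp6 against rrp6 (0.72 ± 0.20). No chromosome stood apart in RNA, where the largest difference between the median of a chromosome and that of all genes was −0.06 (chromosome II, hst34rrp6 against WT). In DRIP-seq it was 0.12 (chromosome V, libraries labelled hst34 against WT). The DRIP signal of HST3 was 291 in WT 1 and 17.9 in WT 2, and 442 and 37.6 in the same libraries with RNase H.

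DRIP signal was linked to RNA level in the untreated libraries labelled hst34. Sequencing depth does not account for it, since with all libraries thinned to similar read numbers the highest Spearman rho of the other 6 was 0.048. An exchange of labels among the 8 libraries would leave 4 of them with no HST4 signal. The fourth lowest had 0.488 of the median gene, which argues against an exchange alone. Libraries from other cells than labelled, in whole or in part, stay possible, because HST4 reached 0.69 in one labelled hst34. HST4 held 21 and 69 reads in the untreated libraries labelled hst34, and 66 and 107 in those with RNase H. A deleted gene should yield no reads, so these values argue against libraries made only from HST4-deleted cells. One hypothesis is that cells without Hst3 and Hst4 may hold more RNA-DNA hybrid at genes with more RNA; it needs the link to vanish with RNase H, and the higher treated library had a rho of 0.049. The HST4 values leave open whether this concerns the strain.

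Break-seq signal was higher in hst34 than in WT in the listed regions. Extra copies carried by the strain would raise the RNA of these regions by about the mean log2 ratio of 0.78. The median RNA change of genes in them was −0.0952, which argues against such copies. The RNA came from other libraries, and copy number in the Break-seq DNA itself was not measured. A preference for highly transcribed regions is not seen, with a median log2 WT RNA level of 8.35 and a random range of 8.18 to 8.52. The choice of regions on these same libraries could produce part of the difference; log2 ratios from independent pairs of libraries correlated at r = 0.331, so the size of the effect may be overstated while the order of regions is partly shared.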
